A study of Mus musculus with 18 samples.

How the data were processed

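RNA was sequenced from 18 libraries of cultured mouse astrocytes, in 6 groups of 3 (alone or with neurons, at day 2, 4 or 7). Per the labels' protocols, astrocytes were grown in serum medium, moved to serum-free N2 medium when confluent and given TdTomato-positive hippocampal neurons on the experimental plates, and cells were detached, sorted by TdTomato fluorescence and lysed. Ribosomal RNA was removed from total RNA with the RiboGone kit, cDNA and libraries were made with SMARTer low-input kits, and 6 libraries at a time were pooled and sequenced on an Illumina HiSeq, per the labels' protocols. The authors deposited read counts per gene. Per the submitters' processing notes, Subread and featureCounts were used with the mouse build mm9. Their versions and whether counting used the strand are not given in the sources used here, so reads of a gene and an overlapping or antisense partner are not told apart, and genes with near-identical copies share reads in a way that is not known. Neither the labels nor the table describe a filter or normalization.

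Columns were matched to samples by their names. The table also held 17 columns of correlations between libraries, which were not used. Rebuilt from the counts, their 153 cells differed from the deposited ones by at most 4.92e-10. Genes are Entrez IDs in the table. Symbols came from RefSeq (24191 of 26301 IDs) and, with a second name table, for 24205. The 2096 IDs left without a symbol keep their number. The reference build, GRCm38, differs from mm9, so no coordinates are given and the reference was used only for names and for which genes are neighbours. All 608 memberships of the gene lists were matched.

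Analysis started from these counts in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 on one model with 6 group means over all 18 libraries, so that all groups share one estimate of the spread, with TMM scaling, filterByExpr by group and Benjamini-Hochberg adjusted p under 0.05. The contrasts were co-culture against alone at each day, their average, day 7 against day 2 in each kind of culture, and the 3 differences of the co-culture effect between days. TMM factors ran from 1.17 to 1.39, except 0.0459 in replicate 1 of astrocytes alone at day 2 and 0.665 in replicate 1 of the day 7 co-culture. Those 2 libraries had a read in 66.2% and 83.1% of the tested genes. Replicate 3 of the day 4 co-culture came next with 85.4%, and the others had 88.3% to 99.1%. The median biological coefficient of variation was 0.587. Replicates were not shown by the labels to be separate animals, so p-values measure the spread between these cultures. No libraries of one group agreed within sampling noise.

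Gene lists, 29 in all, for astrocyte functions, signalling pathways, stress and immune responses and the other cell types a sort could hold, were written before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between members, adjusted over the lists of a contrast. Fixed at the same time were the contrasts, the test, most alternatives and a rule for naming genes. The rule takes, per co-culture contrast, the 6 largest increases and the 6 largest decreases among called genes with a mean log2 CPM of at least 1 and the same direction in all 3 pairs, 5 and 5 for time, the 5 smallest p for differences between days and up to 4 called members per list. It named no gene, since none was called. A further 21 genes are named whatever their result, and 20 of them were tested.

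The labels give all 6 libraries of a replicate number one date, so the numbers pair the samples. In the values, deviations from the group means correlated at 0.108 to 0.469 between libraries of one number and day and at −0.346 to −0.0102 between other numbers, and 18 of 18 libraries were closest to their own number. The main model has no block for the number, so its spread includes differences between dates. The model with the block is an alternative. Others were DESeq2 1.42.0, median-ratio and upper-quartile scaling, other filters and thresholds, robust fitting, only the compared groups, an estimated correlation, fry, and leaving out each replicate. Added after seeing the data were 16 libraries (without the 2 doubtful ones), limma-voom with library quality weights, the set of 8 libraries with the shared gap of 30 genes as a term or on its own, and their combinations with the block. Upper-quartile scaling shifted the median of all genes by up to 0.148 log2 against TMM in the co-culture contrasts, and median-ratio scaling by up to 0.0567.

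The procedure was tested on simulated counts for the real genes, with 200 genes changed, 50 for each fold size. For the day 2 contrast it recovered 0, 15, 25 and 39 of 50 genes at 2-, 4-, 8- and 16-fold, for day 4 it recovered 3, 17, 35 and 45, and for day 7 it recovered 1, 23, 25 and 42. False calls were 3 of 82, 4 of 104 and 1 of 92. With 16 libraries and the block the day 7 contrast recovered 3, 29, 34 and 42. A cholesterol list shifted 2-fold was called in all 4 co-culture contrasts, both with 18 libraries (with 1 false list call, at day 7) and with 16 libraries and the block (0 false). Other groupings of the real libraries of a day gave up to 6, 12 and 7 lists at days 2, 4 and 7. The false calls in simulated counts therefore do not show how often camera calls lists without an effect in these data. Values of some single genes are not reported here.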

Results

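Total RNA was sequenced from mouse astrocytes, the glial cells that supply and regulate neurons. The cells were taken from newborn cortex, cultured for about 2 weeks, and then kept alone or given newborn hippocampal neurons that carry the red fluorescent protein TdTomato. Cells were collected after 2, 4 or 7 days and sorted by TdTomato fluorescence, with astrocytes kept alone setting the gate for cells without it. The title of the series names its question as which astrocyte transcripts contact with neurons regulates. There were 6 groups of 3 libraries. Libraries that share a replicate number share a date in the labels, so each co-culture library has a partner of the same number and day.

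The deposited table held read counts for 26301 genes, of which 22229 had a read in at least 1 library and 16539 passed the expression filter and were tested. Total counts ran from 3242459 reads in replicate 1 of astrocytes alone at day 2 to 32623556 reads in replicate 2 of the day 7 co-culture. In that smallest library 92.5% of the reads fell on a single gene, Entrez ID 19791, which has no symbol in the reference tables used here, and 1820 genes had at least 10 reads. The next smallest, replicate 1 of the day 7 co-culture, had 8966485 reads, of which 40.5% came from the mitochondrial ribosomal RNA mt-Rnr2, against 5.35% to 18.4% in the 16 others. The edgeR and camera tests were also run without these 2 libraries. Below, CPM are counts scaled to library size by TMM, as mean ± SD over n = 3 libraries, fold changes are log2 with their standard error (SE), and a pair is 2 libraries of the same number and day. On that scale a count of 3 reads, taken as the floor, corresponds to 20.2 CPM in the smallest library, 0.504 CPM in the next and 0.0743 to 0.179 CPM in the others, and covers counting error only.

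**Figure D1:**
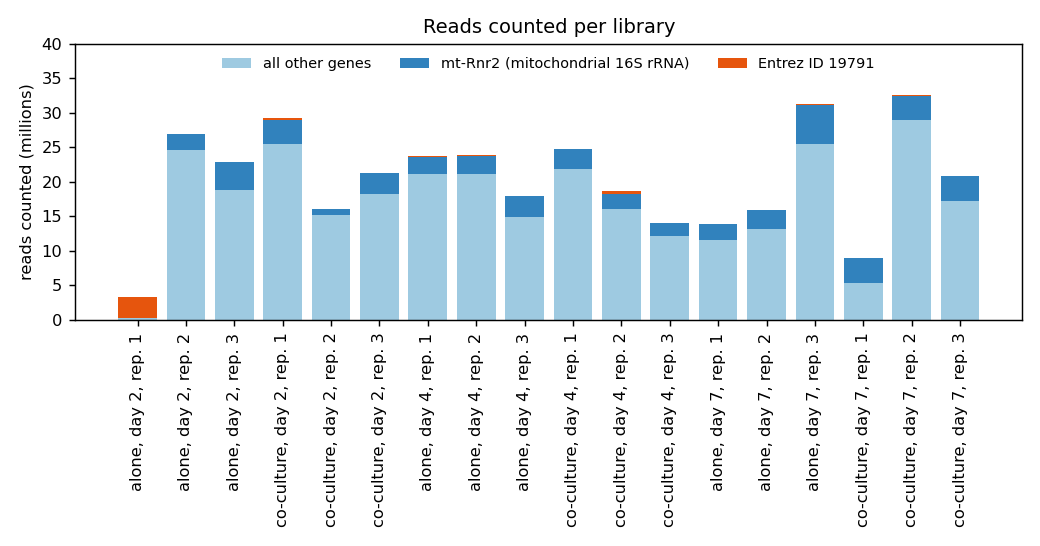
Stacked bars of the reads in each of the 18 libraries (vertical axis, M), with the reads of mt-Rnr2 and of Entrez ID 19791 set apart from those of all other genes. In replicate 1 of astrocytes alone at day 2, 92.5% of the reads belong to ID 19791, and in replicate 1 of the day 7 co-culture 40.5% belong to mt-Rnr2.

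A set of 30 genes had no read in 8 of the 16 other libraries, namely all 6 of replicate 2, replicate 3 of astrocytes alone at day 2 and replicate 3 of the day 7 co-culture. They include Ntrk2, a receptor for the growth factor BDNF, with 11741 to 71965 reads in each of the remaining 8 libraries, Mki67, a marker of dividing cells, and Gas1, a co-receptor of Hedgehog signalling. A position was known for 24 of these genes. Neighbours were looked for among the 20 of them with a median of at least 50 reads in the remaining 8 libraries, and 18 lay in runs. The next most common pattern of this kind held 8 genes. Of the 8 libraries, 4 were co-cultures and 4 were astrocytes alone. The set of 8 holds 1 library of each group, except 2 of astrocytes alone at day 2 and 2 of the day 7 co-culture. The other 10 hold 2 of each group, except that these groups have only their doubtful library there. Only day 4 in the 10 and the average over the days have at least 2 libraries on each side within a set, and the other comparisons rest on a single library of at least 1 group there. With a term for the set in the model, the called lists at days 2, 4 and 7 and on average were the same.

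**Figure D2:**
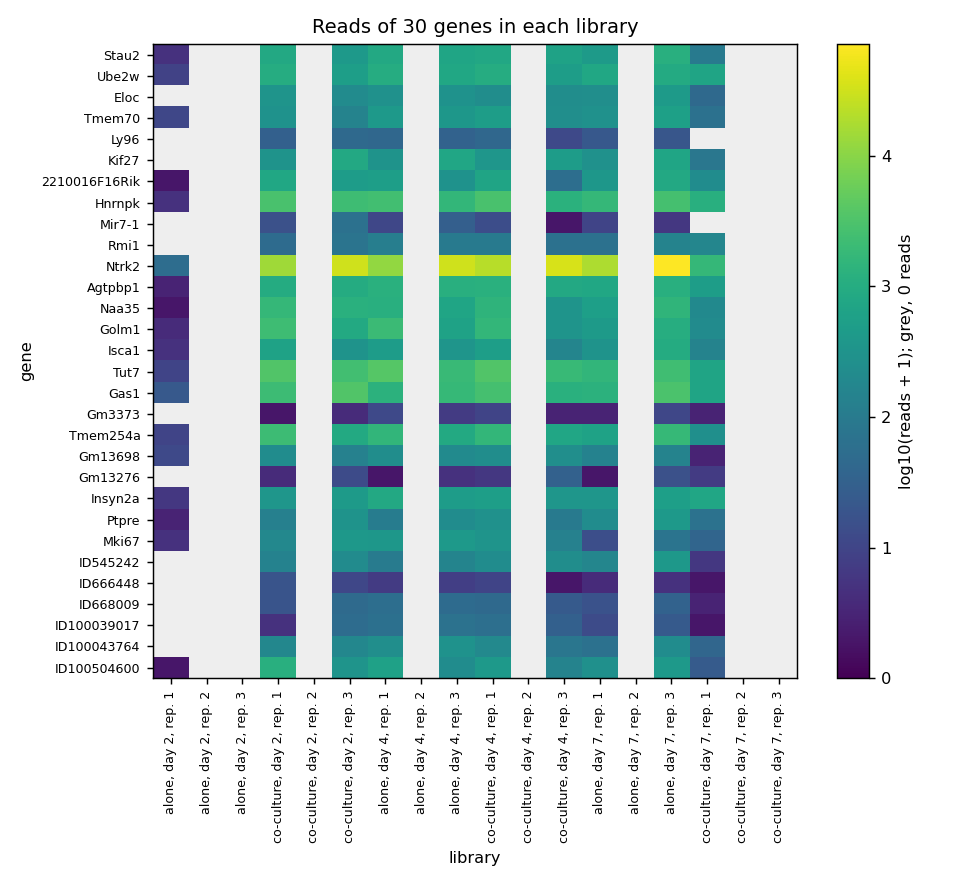
Heat map of log10 of reads plus 1 for the 30 genes (one per line) in the 18 libraries (columns), with 0 reads in grey. All 30 genes are grey in the same 8 libraries, and some also in the 2 doubtful ones.

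Transcripts of neurons were present at low levels in the sorted cells. Dcx, made by young neurons, had 6 reads over the 9 libraries of astrocytes alone and 496 over the 9 co-culture libraries, where the highest library reached 10.7 CPM without normalization. Nefl, a neurofilament, had 0 reads alone and 197 in 5 of the 9 co-culture libraries. Snap25, a synaptic vesicle fusion protein too rare to be tested, had 6 reads in 3 libraries alone and 97 in 2 co-culture libraries. The neurofilament Nefm had reads in 6 libraries alone and 3 in co-culture (46 and 66 reads), and the vesicle protein Syt1 in 8 and 7. Tubb3, a tubulin typical of neurons, had 1904 and 2857 reads and was found in 9 of 9 libraries of both kinds. The general neuron list, 24 tested genes, was not called by limma's camera test on average over the days (adjusted p = 0.905), where its mean log2 fold change was 0.58, its median −0.0065 and the direction of the test lower. Adjusted over the list alone, Dcx, Nefl and L1cam passed on average over the days, and none did over all genes tested.

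At day 2, genes of cholesterol synthesis were higher as a group in astrocytes with neurons than in astrocytes alone. Camera gave the list an adjusted p of 0.00639 (adjusted p = 0.997 with an estimated correlation). Srebf2 (Entrez ID 20788), the transcription factor that drives the pathway, stood at 128 ± 52.4 CPM alone and 223 ± 41.9 CPM in co-culture, a log2 fold change of 0.74 (SE 0.34). It was higher in 3 of 3 pairs and did not pass the test for single genes. Genes of endothelial and mural cells, the cells of blood vessel walls, were lower as a group, with an adjusted p of 0.0392 (adjusted p = 0.245 with an estimated correlation).

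Of the 25 tested cholesterol genes, 21 had a positive fitted change, with a median of 0.31 (0.20 with 16 libraries and the block). The median over the members was 1.17, 0.62 and −0.026 in the pairs of replicates 1, 2 and 3. Of the 11 endothelial and mural genes 9 had a negative fitted change, with a median of −1.79. With 16 libraries and the block 7 did, with a median of −0.52, and the pair medians were −0.41, −0.59 and 0.0077. The median of −1.79 is −1.32 without Pecam1, an adhesion molecule of endothelium, whose only reads at day 2 were 2 in the smallest library (13.4 CPM), below its floor. Abcc9, a channel subunit of mural cells, had 4 reads there (26.9 CPM), and stood over the groups at 9.63 ± 15.0 and 0.353 ± 0.587 CPM. No single gene passed. The edgeR test called 0 of 16539 genes at day 2, with 388 at an unadjusted p under 0.05 (78 higher and 310 lower), DESeq2 called 22 (20 lower and 2 higher, Kif27 and Rmi1, both among the genes without reads in 8 libraries), and limma-voom with library quality weights called 0. Adjusted over the list alone, 0 members of any list passed either. Srebf2, Pecam1 and Abcc9, like every gene named in this and the following comparisons that is not on the list of always-named genes, were chosen after their values were seen.

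The cholesterol call ended without replicate 2 (adjusted p = 0.369), without replicate 2 of astrocytes alone at day 2 (0.223) and without replicate 3 of the day 2 co-culture (0.0868). The endothelial and mural call ended with the replicate block (0.0802), with median-ratio (0.0785) or upper-quartile scaling (0.135), without the 2 doubtful libraries (0.337), and in 18 of 21 leave-outs. Single libraries left out gave 0.0519 to 0.323 where it ended, the highest without replicate 1 of the day 2 co-culture, and it stood only without replicate 3 of the co-culture at day 2, replicate 1 at day 4 or replicate 2 at day 7. Without replicate 1 of astrocytes alone at day 2, the smallest library, and without both doubtful libraries 3 lists were called, cholesterol synthesis and TGF-beta and YAP targets higher and astrocyte identity lower. Without both, each had an adjusted p of 0.822 with an estimated correlation.

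At day 4, 4 lists were higher in co-culture as groups: glycolysis and lactate, astrocyte identity, transmitter uptake with potassium and gap junction genes, and the A1 list of genes seen in astrocytes activated by inflammation. Each had adjusted p = 0.944 with an estimated correlation, and 0.0320 or less with the preset one. Among the glycolysis genes, Pfkl (Entrez ID 18641), the liver-type phosphofructokinase, stood at 57.7 ± 6.79 CPM alone and 78.0 ± 6.25 CPM in co-culture (log2 fold change 0.44, SE 0.26). Gys1 (14936), a glycogen synthase, stood at 34.5 ± 5.33 and 48.7 ± 12.8 CPM (0.50, SE 0.33), and both were higher in 3 of 3 pairs. Among the identity genes, Fgfr3 (14184), a growth factor receptor of astrocytes, stood at 72.7 ± 25.4 and 104 ± 21.3 CPM (0.52, SE 0.41), and Sox9 (20682), a transcription factor of the lineage, at 112 ± 59.1 and 151 ± 35.5 CPM (0.43, SE 0.49), both higher in 3 of 3 pairs. The glutamine transporter Slc38a3 (132 ± 52.2 and 167 ± 70.8 CPM) and the A1 gene Amigo2 (1.45 ± 0.382 and 4.48 ± 4.53 CPM) were higher in 2 of 3 pairs.

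In camera, the adjusted p was 0.000685 for glycolysis and lactate (19 of 23 members higher, median 0.30) and 0.0120 for astrocyte identity (24 of 29, median 0.28, mean 0.070). It was 0.0120 for transmitter uptake (16 of 19, median 0.30) and 0.0320 for the A1 list (10 of 13, median 0.45). The uptake and identity lists share members. The edgeR test called 0 genes at day 4, with 61 at an unadjusted p under 0.05 (15 higher and 46 lower; 216 with 16 libraries and the block). DESeq2 and limma-voom with library quality weights also called 0, and 0 list members passed when adjusted over the list alone.

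**Figure D3:**
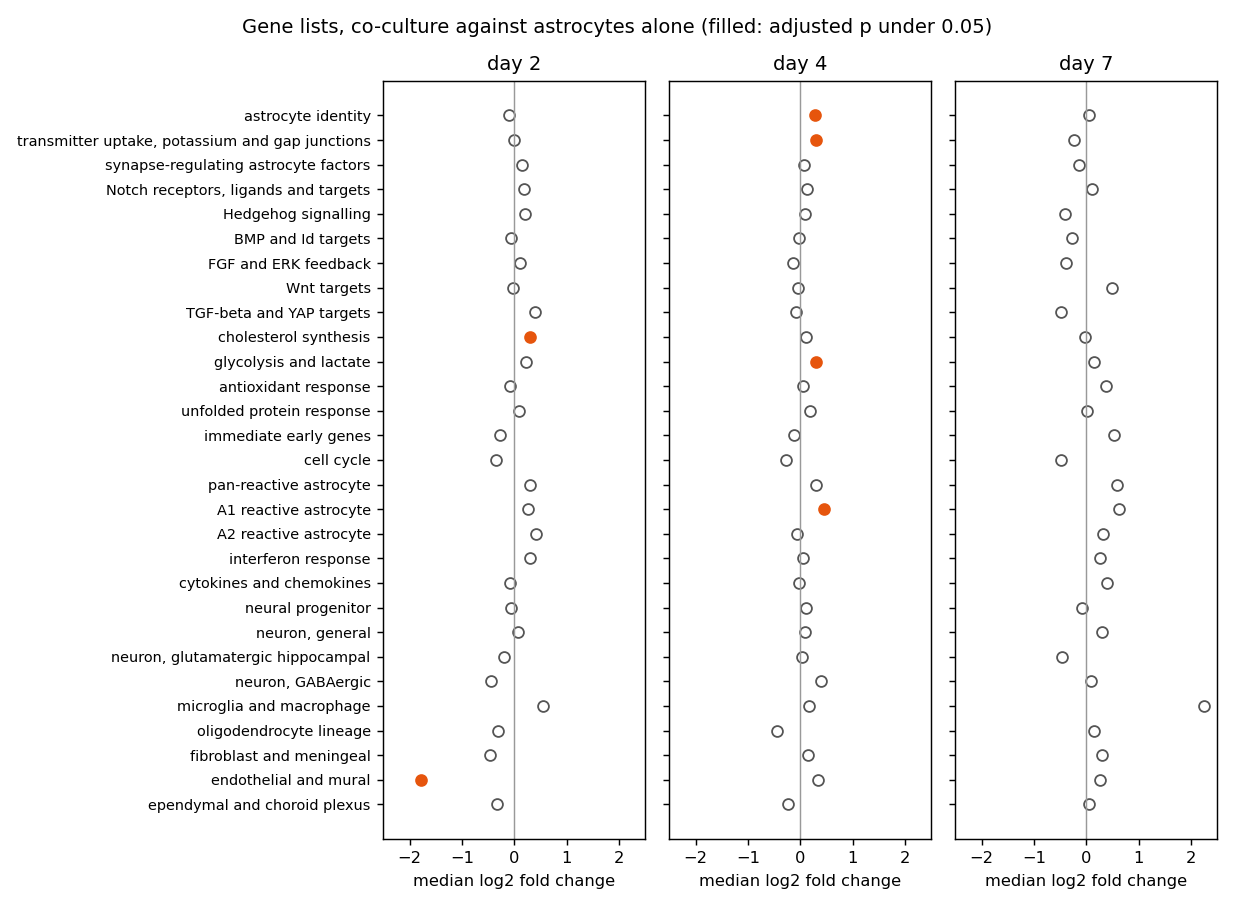
Median log2 fold change (co-culture against alone) of the tested members of each of the 29 gene lists at days 2, 4 and 7, with filled points for an adjusted p under 0.05 in camera. Filled points appear for 2 lists at day 2, 4 at day 4 and 0 at day 7.

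Without replicate 1 the adjusted p was 0.0554 for glycolysis, 0.944 for identity, 0.944 for uptake and 0.588 for A1, and without replicate 1 of astrocytes alone at day 4 identity (0.443) and uptake (0.980) turned lower and A1 was at 0.336. Without replicate 3 of the day 4 co-culture identity was at 0.863 and uptake turned lower (0.589), and without its replicate 2 identity was at 0.0539 and A1 at 0.442. Without replicate 1 of the day 7 co-culture, which enters through the shared spread, identity was at 0.0878, uptake at 0.101 and A1 at 0.0878, and without both doubtful libraries at 0.0698, 0.102 and 0.0652. With those 16 libraries and the block all 4 lists were called (9.47e-05 for glycolysis, 0.000364 for identity, 0.00316 for uptake and 0.0385 for A1). With an estimated correlation as well the adjusted p was 0.691 for glycolysis and uptake and 0.804 for identity and A1. Uptake also ended without replicate 1 of astrocytes alone at day 2 (0.0548) or replicate 2 at day 4 (0.101). A1 also ended without replicate 3 of astrocytes alone at day 4 (0.107), without replicate 1 of the day 4 co-culture (0.0524) and with genes of at least 10 CPM only (0.0583). The count of called lists was 7 without replicate 2 of astrocytes alone at day 4 or replicate 3 of the day 4 co-culture, and 9 without replicate 3 of astrocytes alone at day 4. Within the other 10 libraries, 2 against 2 at day 4, there were 5, the same 4 with cholesterol synthesis, and edgeR called 0 genes.

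At day 7 no list and no gene passed the test. Genes of microglia and macrophages, the immune cells of the brain, had the largest median difference, with 20 of 20 tested members fitted higher in co-culture, a median log2 fold change of 2.24 and an adjusted p of 0.102 in camera. Laptm5 (Entrez ID 16792), a lysosomal protein of blood-derived cells, stood at 2.10 ± 3.10 CPM alone and 43.0 ± 38.2 CPM in co-culture, where the 3 libraries held 73.0, 56.1 and 0 CPM. The 73.0 CPM belong to the doubtful library of replicate 1. Most members were high in replicate 2 of both kinds, as in Lyz2, a lysozyme of macrophages, with 165 CPM alone and 187 CPM in co-culture there and at most 10.9 CPM in the other day 7 libraries. Unlike Lyz2, Laptm5 rose within replicate 2, from 5.67 CPM alone to 56.1 CPM. The pair medians of the list were 0, 2.10 and −0.40 in replicates 1, 2 and 3, so its difference came mainly from replicate 2. Genes of FGF and ERK feedback had 16 of 20 members fitted lower, among them the transcription factor Etv5 (131 ± 19.3 and 65.6 ± 24.2 CPM, −0.99, SE 0.40, and −0.64 with 16 libraries and the block) and the growth factor Fgf1 (167 ± 78.9 and 57.9 ± 56.1 CPM, −1.52, SE 0.71), both lower in 3 of 3 pairs.

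The adjusted p at day 7 was 0.102 for the FGF list, the antioxidant list (19 of 23 higher, median 0.37, and 0.23 with 16 libraries and the block) and the interferon list (14 of 24 higher, median 0.25) as well. With the replicate block the microglia (adjusted p = 0.00908) and interferon (0.0194) lists passed, with adjusted p = 0.808 for both when the correlation was estimated as well. The medians of the interferon list in the pairs of replicates 1, 2 and 3 were −0.51, 1.70 and 0.085, so its difference came mainly from replicate 2. There the library of astrocytes alone was low rather than the co-culture high. The list mean of replicate 2, in log2 CPM against the mean of the 16 libraries, was −1.33 alone and 0.52 in co-culture. At day 4 it was 0.56 and 0.52, and at day 2 it was 0.99 and 1.09. Without the 2 doubtful libraries 7 lists passed, 6 higher and 1 lower, with 0.452 the lowest adjusted p when the correlation was estimated. The lower one was FGF and ERK feedback (0.00252, and 0.00501 with the block as well). With 16 libraries and the block transmitter uptake, higher at day 4, was lower at day 7. There 15 of 20 members were lower, with a median of −0.41 and an adjusted p of 0.00711 (0.491 with an estimated correlation). With all 18 libraries uptake was at 0.459. Leaving out single libraries gave calls at day 7 without replicate 1 (6 lists), 2 (1 list, microglia) or 3 (1 list, antioxidant) of astrocytes alone at that day, and without replicate 1 (7 lists) or 3 (2 lists, interferon and microglia) of the co-culture. The edgeR test called 0 genes, with 1549 at an unadjusted p under 0.05 (1340 higher and 209 lower), and 427 such genes with 16 libraries and the block. DESeq2 called 5, all higher: Vcan, Fbln1, Snord17, Scarna6 and Gm15834. Limma-voom with library quality weights called 0, and edgeR with the block called 1, the keratinocyte envelope gene Lce1g (adjusted p = 0.00835), whose mean of 86.7 ± 150.2 CPM came almost wholly from replicate 1 (260.2 CPM). Adjusted over the list alone, Vcan, a matrix proteoglycan, and Ptgs2, a prostaglandin synthase, passed in their lists. Vcan stood at 30.2 ± 15.2 CPM alone and at 461, 103 and 32.6 CPM in the 3 co-culture libraries (2.72, SE 0.67, and 1.07 with 16 libraries and the block). Ptgs2 stood at 9.0 ± 1.59 and 73.8 ± 98.6 CPM, with 188 CPM in replicate 1 (3.03, SE 0.89, and 0.67 with 16 libraries and the block).

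With 16 libraries and the block edgeR called 18 genes, of which 17 are among the 30 without reads in the 8 libraries. The remaining one was Sema3c, a secreted guidance protein (1.53, SE 0.25, adjusted p = 0.0149, against 1.22, SE 0.48, with all 18 libraries). With the 30 genes left out as well its change and SE were the same and its adjusted p 0.238, so the call depended on their part in the adjustment and the size of the change did not.

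On average over the 3 days, glycolysis and lactate genes were higher as a group in co-culture. Camera gave an adjusted p of 0.0386 (adjusted p = 0.940 with an estimated correlation). Of 23 members 19 were fitted higher, with a median log2 fold change of 0.19 (0.12 with 16 libraries and the block). Gpi1 (Entrez ID 14751), a glucose phosphate isomerase, had a log2 fold change of 0.44 (SE 0.18, and 0.27 without the 2 doubtful libraries), and Ldhb (16832), a lactate dehydrogenase subunit, one of 0.42 (SE 0.23). With the replicate block 5 lists were higher, the others being A1, cholesterol synthesis, interferon and microglia (adjusted p = 0.0411, 0.0415, 0.0158 and 0.0226). With an estimated correlation as well all 5 had adjusted p = 0.886. Averaged over the days edgeR called 0 genes, with 689 at an unadjusted p under 0.05 (386 higher and 303 lower), and DESeq2 and limma-voom with library quality weights called 0. Adjusted over the list alone 4 members passed, Dcx, Nefl, L1cam and the ependymal regulator Mcidas. Mcidas had no read in the day 2 co-culture and 0.483 ± 0.428 CPM alone.

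The glycolysis call ended with upper-quartile scaling (0.0557), with genes of at least 10 CPM only (0.249) and without replicate 3 (0.211). It also ended without replicate 1 of astrocytes alone at day 4 (0.0625), replicate 3 of the day 4 co-culture (0.0746), or replicates 2 (0.0778) or 3 (0.127) of the day 7 co-culture, and within the set of 8 (0.261) and the other 10 (0.370). The count of lists was 3 to 5 without replicate 1 of astrocytes alone at day 2 (3), replicate 3 of the day 2 co-culture (5), replicate 2 of astrocytes alone at day 4 (4), replicates 1 (4), 2 (3) or 3 (3) of astrocytes alone at day 7, or replicate 1 of the day 7 co-culture (4), and 2 without 6 others. Within the set of 8, where 4 of the 6 groups are single libraries assumed to vary like the rest, edgeR called 0 genes and camera 6 lists (5 higher and 1 lower). Within the other 10, where 2 groups are single doubtful libraries, edgeR called 0 genes and camera 0 lists.

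The genes named whatever their result, 20 of them tested, gave 0 calls in the 3 days and on average. Gfap (14580), the intermediate filament of astrocytes, varied more between replicates than between groups, with 611 ± 597 and 678 ± 705 CPM at day 2 and 741 ± 749 and 861 ± 958 CPM at day 7 (log2 fold change 0.22, SE 1.16, and −0.21 with 16 libraries and the block). Kcnj10 (16513), a potassium channel of mature astrocytes, stood at 155, 226 and 1927 CPM in the 3 libraries of astrocytes alone at day 2 and at 243, 202 and 2087 CPM in co-culture. At day 7 Kcnj10 was lower in 3 of 3 pairs (853 ± 419 and 364 ± 319 CPM, −1.23, SE 1.00), and with 16 libraries and the block its change was −1.72 (SE 0.44, adjusted p = 0.681). The glutamate transporter Slc1a2 stood at 97.7 ± 18 and 207 ± 214 CPM at day 7 (1.09, SE 0.91, and 0.08 with the block). The gap junction gene Gja1 was higher in 3 of 3 pairs at day 4 (0.47, SE 0.66) and day 7 (0.58, SE 0.66), but at day 7 the change was 0.10 without the 2 doubtful libraries and turned to −0.14 with the block as well. The Notch target Hes1 was lower in 3 of 3 pairs at day 7 (28.4 ± 25.1 and 13.0 ± 7.71 CPM, −1.12, SE 0.73, and −0.55 with 16 libraries and the block). Thbs1, a secreted factor that promotes synapses, was higher in 3 of 3 pairs at day 2 (1736 ± 636 and 3240.4 ± 1885 CPM, 0.90, SE 0.56). Tubb3 was higher in 3 of 3 pairs at day 7 (7.64 ± 3.42 and 19.1 ± 17.7 CPM, 1.32, SE 0.74), and the change was 0.25 without the 2 doubtful libraries. None of these differences passed the edgeR test, with or without the block. Mki67 is among the genes without reads in 8 libraries, so no fold change is given for it.

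**Figure D4:**
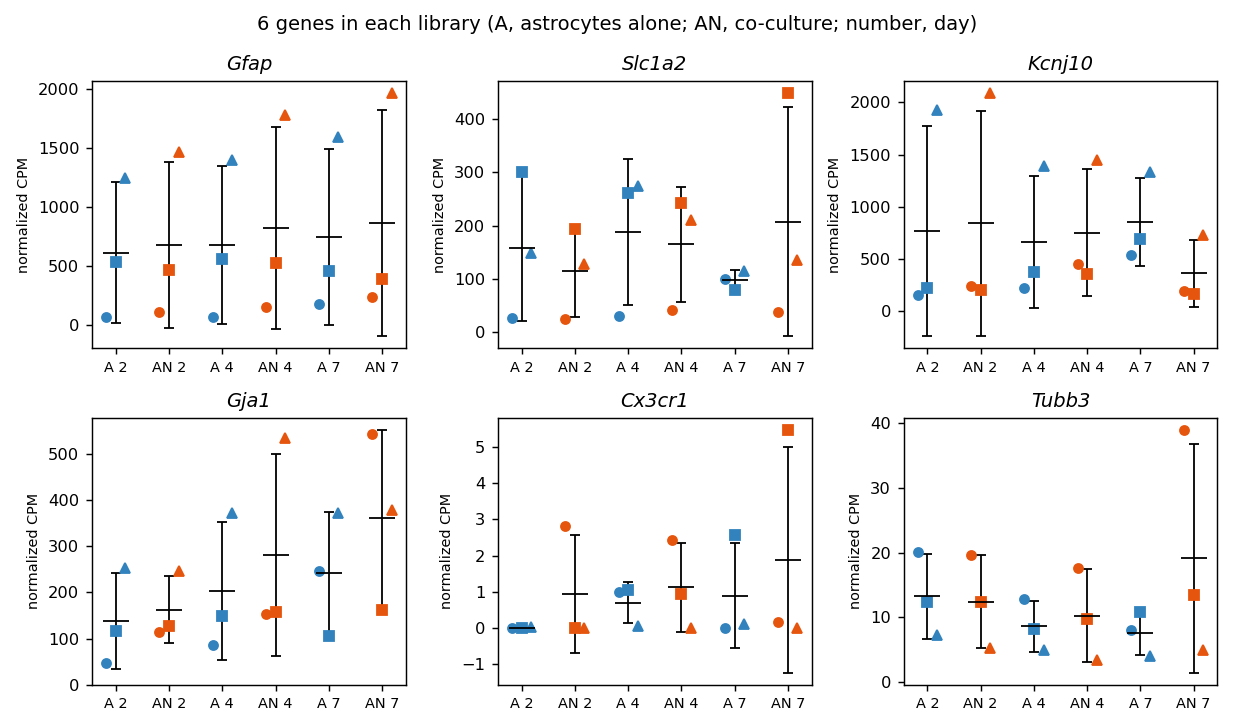
Normalized CPM of Gfap, Slc1a2, Kcnj10, Gja1, Cx3cr1 and Tubb3 in each library, with the mean and SD of each group of 3 (blue, alone; orange, co-culture; circle, square and triangle, replicates 1, 2 and 3). For Kcnj10 at day 2, replicate 3 stands at 1927 CPM alone and 2087 CPM in co-culture, far above replicates 1 and 2 of both groups.

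From day 2 to day 7, no gene changed past the threshold in astrocytes alone or in co-culture. In co-culture, Srxn1 (Entrez ID 76650), which repairs oxidised peroxiredoxins, stood at 49.4 ± 12.4 CPM at day 2 and 246 ± 141 CPM at day 7 (log2 fold change 2.32, SE 0.48, adjusted p = 0.271). Gclc (14629), the enzyme that limits glutathione synthesis, stood at 79.1 ± 27.7 and 255 ± 111 CPM (1.69, SE 0.42, and 1.11 with 16 libraries and the block). The contractile genes Tagln (115 ± 85.2 and 23.5 ± 17.8 CPM) and Myl9 (178 ± 131 and 33.9 ± 25.5 CPM) and the replication gene Uhrf1 (11.9 ± 3.25 and 1.77 ± 1.39 CPM) had lower means at day 7. In astrocytes alone edgeR called 0 genes, with 183 at an unadjusted p under 0.05 (68 higher and 115 lower; 526 with 16 libraries and the block). DESeq2 called 3 there (Kif27 and Rmi1, both among the genes without reads in 8 libraries, and 3110070M22Rik), and limma-voom with library quality weights 0. In co-culture edgeR called 0, with 2181 at an unadjusted p under 0.05 (1656 higher and 525 lower; 1152 with 16 libraries and the block), DESeq2 called 242 (223 higher and 19 lower, Srxn1, Gclc and Uhrf1 among them), limma-voom with library quality weights 0, and edgeR with the block 1 (Lce1g, adjusted p = 0.0354).

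Whether the co-culture effect differed between days was tested for single genes, and none passed. The edgeR test called 0 genes between days 2 and 4 (175 at an unadjusted p under 0.05), 0 between days 2 and 7 (905) and 0 between days 4 and 7 (507), and limma-voom with library quality weights called 0 in each. With 16 libraries and the block 248, 471 and 263 had an unadjusted p under 0.05. DESeq2 called 0, 3 and 0, the 3 being the microglial gene Aif1, Hmcn1 and Kif27, the last among the genes without reads in 8 libraries. Without replicate 2 edgeR called 1 between days 2 and 7, the pseudogene Nutf2-ps2. Median standard errors of these differences were 0.98, 0.98 and 0.95, against 0.71, 0.67 and 0.68 for the effect within days 2, 4 and 7.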

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

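The tests on the difference of gene lists between days and all tests of the explanations for the genes without reads were chosen only after the results were seen. Groups of 3 libraries were not searched for single deviating samples. The co-culture effect differed between days 2 and 4 for 2 lists, out of 87 tests of 29 lists over 3 pairs of days. The endothelial and mural list differed with an adjusted p of 0.0353 in camera (median difference 2.02, higher at day 4; adjusted p = 0.155 with an estimated correlation, 0.579 with 16 libraries and the replicate block, where the median difference was 0.94). The fibroblast and meningeal list differed with an adjusted p of 0.0372 (median difference 0.35, higher at day 4; adjusted p = 0.966 with an estimated correlation, 0.353 with 16 libraries and the block). With the replicate block astrocyte identity (0.0244) and transmitter uptake (0.0458) also differed between days 2 and 4, both higher at day 4. With that block cholesterol synthesis (0.0375) differed between days 2 and 7 and uptake (0.00110) between days 4 and 7, both lower at day 7. With an estimated correlation as well these had adjusted p = 0.962, 0.962, 0.980 and 0.872. Without the 2 doubtful libraries, the endothelial and fibroblast lists had adjusted p = 0.470 and 0.224. Astrocyte identity then differed between days 2 and 4 (0.000645), 5 lists between days 2 and 7 and 1 between days 4 and 7, and with the block as well 2, 5 and 7 lists. None passed with an estimated correlation (lowest adjusted p = 0.672 with 16 libraries and 0.374 with the block as well).

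The 30 genes without reads in 8 libraries are a pattern of the samples rather than of the groups. Depth is argued against, since all 30 would have at least 3 reads in the smallest of the 8 libraries at the rates of the others, and Ntrk2 alone would have 21548. The co-culture or the day is argued against as well, since 4 of the 8 libraries are co-cultures and all 3 days are among them. A separate alignment or counting run for these 8 libraries, one that lost whole stretches of the genome, may account for it. Of the 20 genes with a position and a median of at least 50 reads, 18 lie beside another of them, against at most 2 in 1000 random draws. The runs go from Stau2 to Tmem70 on chromosome 1, Kif27 to Gas1 on chromosome 13 and Insyn2a to Mki67 on chromosome 7. Of the genes with a difference for the set of 8 in a model with that term, 24 passed and all 24 were lower.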

How the results depend on the processing

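Tests with 16 libraries, limma-voom, the set of 8 and their combinations with the block or an estimated correlation were chosen only after the result was seen. Where a value moved and no reason is given, the cause was not tested. Single genes: edgeR called 0 in all 9 contrasts, and this stood with other thresholds, scalings, filters, robust fitting and only the compared groups. With the replicate block it called 1 at day 7 and 1 over time in co-culture, both Lce1g, and changed no other gene call. DESeq2 called 22 at day 2, 5 at day 7, 3 over time alone, 242 over time in co-culture and 3 between days 2 and 7. With 16 libraries and the block edgeR called 16 at day 2, 18 at day 7, 17 over time alone, 17 over time in co-culture, and 14, 23 and 15 between days 2 and 4, 2 and 7, and 4 and 7. With the 30 genes without reads left out as well it called 0 in each. Limma-voom with weights and the block called 6 over time alone and 20 between days 2 and 7. A term for the set of 8 gave 1 at day 7 (Lce1g). Within the other 10 libraries edgeR called 11 at day 2, 4415 at day 7, 13 and 4617 over time alone and in co-culture, and 2, 1299 and 2404 between days. Each of these rests on a single doubtful library in at least 1 group, assumed to vary like the rest, and nothing is drawn from them. Leaving out replicates gave 0 throughout, except 0 to 1 between days 2 and 7.

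Lists: the main counts at days 2, 4, 7 and on average were 2, 4, 0 and 1. An estimated correlation and fry gave 0, 0, 0 and 0, as did an estimated correlation with the block, with 16 libraries, or with 16 libraries and the block. The replicate block gave 1, 4, 2 and 5, and changed no other list call at these days and on average than those given with each result. Over time it added FGF and ERK feedback in co-culture (adjusted p = 0.108 without and 0.0498 with it). Median-ratio scaling gave 1 at day 2. Upper-quartile scaling gave 1 at day 2, 1 at day 7 (microglia) and 0 on average, and the 10 CPM filter 1 at day 2 and 0 on average. The 16 libraries gave 3 at day 2, 1 at day 4, 7 at day 7 and 4 on average. The 16 libraries with the block gave 1 at day 2, 5 at day 4 (the main 4 and cholesterol), 10 at day 7 and 7 on average, with or without the 30 genes, and with a term for the set of 8 gave 2 at day 2, 5 at day 4, 12 at day 7 and 7 on average. A term for the set of 8 with all 18 libraries changed no list call. Within the set of 8 there were 1, 0, 15 and 6, with 1 library in at least 1 group of each day (1 against 1 at day 4), and within the other 10 there were 0 at day 2, 5 at day 4, 0 at day 7 and 0 on average, with single doubtful libraries at days 2 and 7. Leaving out replicates gave 0 to 3 at day 2, 0 to 9 at day 4, 0 to 8 at day 7 and 0 to 5 on average. Called lists kept their direction in all alternatives, except astrocyte identity (35 of 37) and transmitter uptake (34 of 37) at day 4. Their adjusted p ranged from 2.87e-05 to 0.997 for cholesterol at day 2, 0.0232 to 0.932 for endothelial and mural, 4.83e-05 to 0.990 for glycolysis, 7.53e-06 to 0.990 for identity, 9.46e-07 to 0.990 for uptake and 0.000827 to 0.990 for A1 at day 4, and 0.000984 to 0.953 for glycolysis on average. Median, mean and test differed in sign for 4, 7, 10 and 8 of the 29 lists at days 2, 4, 7 and on average, none of them called.

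For single named genes, the alternatives compared were the block, DESeq2, scalings, filters, 16 libraries with and without the block, and the leave-outs. The 20 genes always named, none of them called, stayed without a call in all 2300 alternative values for the 3 days and the average. There were 205 changes of sign among these values, and only 19 of 80 pairs of gene and contrast kept one sign throughout. Between days 2 and 7 Mki67, one of the 30 genes without reads in 8 libraries, was called with 16 libraries and the block (adjusted p = 0.0104). Of the genes named after their values were seen, 30 were compared and kept their call in 5141 of 5148 values for the days, the average and time, the 7 new calls being Vcan, Srxn1, Gclc and Uhrf1 with DESeq2, Lce1g with the block (2 contrasts) and Sema3c with 16 libraries and the block. Of their 180 pairs of gene and contrast, 102 kept one sign throughout. Outside these alternatives Lce1g was called at day 7 with the term for the set of 8, and Vcan and Ptgs2 within the other 10. Depth limits the smallest library most, where 3 reads correspond to 20.2 normalized CPM.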

Other observations

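The list tests over time, the splits of gene counts and of lists over time, and the tests of a lower astrocyte share, of the doubtful library and of member correlation were chosen only after the result was seen. From day 2 to day 7, genes of the TGF-beta and YAP response and of the cell cycle were lower and antioxidant genes higher as groups, both in astrocytes alone and in co-culture. With an estimated correlation no list passed (lowest adjusted p = 0.526 alone and 0.248 in co-culture). In astrocytes alone camera called 9 lists. TGF-beta and YAP targets, which include contractile and matrix genes, had 18 of 23 members lower (median log2 fold change −0.50, adjusted p = 4.95e-05), cell cycle genes 37 of 38 (−1.12, adjusted p = 4.95e-05), and fibroblast and meningeal genes 16 of 18 (−1.26, adjusted p = 9.64e-05). Antioxidant genes had 19 of 23 members higher (0.64, adjusted p = 0.0118), and unfolded protein response genes 18 of 21 (0.45, adjusted p = 0.0198, and 0.242 with 16 libraries and the block). Endothelial and mural genes had 8 of 11 lower (−1.22, adjusted p = 0.0295, and 0.708 with 16 libraries and the block). Cytokine (0.0253), interferon (0.0295) and immediate early genes (0.0295) were lower too. The cytokine medians of replicates 1, 2 and 3 alone were 1.89, −3.50 and 0.12. Those of the interferon list were 1.29, −2.27 and −0.0036, so the fall of both lists came mainly from replicate 2. Immediate early genes had 0.075, −0.45 and −0.63. Replicate 1 holds the doubtful day 2 library here. The interferon list was at 0.175 with 16 libraries, at 2.30e-05 with the block as well and at 0.569 with an estimated correlation added. In co-culture camera called 5 lists. Fibroblast and meningeal genes were not among them, with a median of −0.90 there. TGF-beta and YAP targets had 22 of 23 members lower (−1.17, adjusted p = 2.70e-09), antioxidant genes 22 of 23 higher (0.98, adjusted p = 5.23e-07), and cell cycle genes 24 of 38 lower (−1.22, adjusted p = 0.000610), with unfolded protein response genes higher (0.0359) and synapse-regulating factors lower (0.0499), both lost without the 2 doubtful libraries (0.161 and 0.118) and called again with the block as well (0.0425 and 0.0249).

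The direction over time held in each replicate number for the TGF-beta and YAP targets, the cell cycle and the antioxidant genes, and not for the unfolded protein response, where replicate 2 had a median of −0.44 alone and −0.12 in co-culture. The median of the TGF-beta and YAP targets was −0.84, −0.35 and −0.45 alone and −2.88, −0.76 and −0.49 in co-culture, and that of the antioxidant genes 1.08, 0.02 and 0.82 alone and 1.05, 0.72 and 1.11 in co-culture. The values of replicate 1 each rest on a doubtful library, at day 2 alone and at day 7 in co-culture. The 0.02 of replicate 2 alone is hardly a change. Adjusted over the list alone, 15 members passed in co-culture, among them the actin-binding genes Tagln, Acta2, Cnn2 and Myl9 and the glutathione and peroxide genes Gclc, Gclm, Srxn1 and Prdx1. With 16 libraries and the block 0 TGF-beta and YAP targets passed in place of 8, and 9 antioxidant genes in place of 6. Whether these changes differ between the kinds of culture was tested, and the adjusted p was 0.147 for the TGF-beta and YAP targets and 0.111 for the antioxidant genes. Of the 10 splits of the 6 libraries, the real one gave 9 lists alone and 5 in co-culture and the highest other 11 and 7. In each case 5 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Of the 3 other splits that part all pairs, the highest gave 9 and 3.

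Genes of microglia were fitted higher in the day 7 co-culture, and the tests leave the source open. Without the doubtful co-culture library the members had a median log2 fold change of 2.55 and a lower quartile of 1.49. Camera gave an adjusted p of 0.00403 (0.102 with it), and 0.902 without both doubtful libraries and with an estimated correlation. This leave-out cannot decide whether that library is the source, because replicate 2, high in both kinds of culture, then weighs more in co-culture. The pair of replicate 2, which does not hold that library, had a median of 2.10. A larger share of microglia among the sorted cells may be one source, because the sort removes TdTomato-positive cells and not microglia; the pair medians were 0, 2.10 and −0.40, which at face value meets the bound set beforehand against it (at or below 0 in at least 2 pairs), but the upper quartiles in those pairs reach 1.85 and 0.026 and one of them holds the doubtful library. Of its 20 tested members 20 had reads in astrocytes alone, 14 of them at a mean of at least 1 CPM, among them Lyz2 (39.4 CPM), and 0 are in another list. A lower share of astrocytes could also raise it, and stays open: with 16 libraries and the block the medians of the oligodendrocyte, endothelial and fibroblast lists were −0.14, 0.15 and 0.74.

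Astrocyte identity genes were higher in co-culture at day 4. Correlation between the members may account for that call, since its adjusted p was 0.944 with an estimated correlation. That setting called 0 lists at every day and on average, so the loss of the call does not set this list apart and cannot decide the question. A single culture date could also be a source, and stays open, since the pair medians were 0.99, −0.075 and 0.29 and that of replicate 2 lies within the spread of the members. The call depended on single libraries: camera gave an adjusted p of 0.944 without replicate 1. It gave 0.443, with the direction lower, without replicate 1 of astrocytes alone at day 4, and 0.863 without replicate 3 of the day 4 co-culture. A biological effect of the neurons, which the design names, stays open as well and was not tested further.

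For the co-culture counts of lists at days 2, 4 and 7, the real splits gave 2, 4 and 0 lists and the highest other split 6, 12 and 7. Among 10 splits, 8, 7 and 10 gave as many, and 10 splits are too few for a share under 0.05. Of the 3 other splits at each day that part all pairs, the highest gave 2, 3 and 5. For the average, 90 of 100 splits gave as many lists as the real 1, with 11 the highest, so chance cannot be excluded, and of the 4 others that part all 9 pairs the highest gave 5. For single genes the real count was 0 in every contrast, so all splits (10 of 10 within days or over time, 100 of 100 for the average and the differences between days) gave as many. The highest other split gave 0, except 149 for the average, 1 over time in co-culture and 67 between days 2 and 7.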
